A study of Mus musculus with 4 samples.

How the data were processed

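RNA of splenic T cells activated for 3 days was sequenced in 4 libraries, 1 each for wild type and Cers6 knockout mice at 2 and 8 months of age, and groups were taken from the labels. The submitters' processing notes name CASAVA and STAR and the builds GRCm38 and mm10, without versions. The counting tool, the annotation, the strandedness and the tool of the authors' tests are not given in the sources used here. The deposited table holds 35275 genes with coordinates and lengths. Per the file headers it gives raw counts of reads per gene for each library. The deposited FPKM values equal the counts divided by the deposited length and the library total, on the usual FPKM scale, within 1e-6 in all 35275 genes of each library, and were not used further. The authors' log2 fold changes and the authors' adjusted p-value columns for 4 contrasts were used only to count marked genes, and the authors' marks match an adjusted p-value under 0.005 with a log2 fold beyond 1, with 0 exceptions.

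Of the genes, 13774 had no count in any library. Library totals were 24239344, 21886108, 18145555 and 20342672 counts, in the order wild type at 2 and 8 months and knockout at 2 and 8 months. Mitochondrially encoded genes took 1.90%, 2.05%, 1.49% and 1.72% of the counts and immunoglobulin genes 0.417%, 0.798%, 0.386% and 0.563%. A count of 3, the limit that a count of 0 allows, corresponds to 0.131, 0.142, 0.174 and 0.128 scaled CPM. There were 27 symbols turned into dates, which were restored by gene identifier. GENCODE M21 held 34490 of the identifiers, 24919 with identical coordinates, and coordinates printed are those of the deposited table.

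Scaling used TMM factors (edgeR 4.0.16, R 4.3.3), which were 0.956, 0.964, 0.951 and 1.14 for the tests and 0.947, 0.968, 0.949 and 1.15 for the printed CPM levels and single-library contrasts, over all genes with a count. Tests used edgeR quasi-likelihood with age and genotype as additive terms on 13906 genes past filterByExpr, with Benjamini-Hochberg adjustment at 0.05. The model leaves 1 residual degree of freedom, with 15.4 prior degrees of freedom and a biological coefficient of variation of 0.267, and any real difference of a genotype effect between ages counts as spread. Each of the 4 contrasts of single libraries was counted at 2-fold on log2 CPM with a prior count of 2, among 12133 genes with 2 CPM or more in at least 1 library, without a test. Counting intervals of ratios and shares are exact at 95% (scipy 1.17.1, Clopper-Pearson), and a ratio against 0 counts is given as a bound against 3 counts in that library. Printed folds of single-library contrasts include the prior count and their intervals do not. At low counts a fold thus lies nearer to no change than the plain ratio that its interval covers. Correlations and overlaps of 2-fold genes expected with no effect come from 100 simulations. Counts expected from counting error alone are means over a smaller number of simulated draws. The test was checked on simulated data: of 50 genes changed per fold size, 20%, 82%, 100% and 96% were recovered for genotype at 2, 4, 8 and 16-fold, with 5 false calls, and 38%, 88%, 98% and 98% for age, with 9 false calls. The simulated changes were additive and every library had the fitted spread. The rates thus do not cover a genotype effect that differs between ages or a library that stands apart.

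The 50 gene lists hold 1301 entries, of which 1296 matched the table. They were tested with camera (limma 3.58.1, preset correlation 0.01) on voom values, Benjamini-Hochberg adjusted over the lists within each effect, and medians were compared with 10000 random lists of the same size and similar expression. Genes were named by rule. The ceramide synthases come first. Then follow the 10 higher and 10 lower genes per effect with the largest mean log2 fold, among genes at 2-fold or more in the same direction in both contrasts with a mean of 5 CPM or more. Predicted or clone models, pseudogenes, and immunoglobulin and T cell receptor segments were left out. The 6 highest and 6 lowest differences of the age effect and up to 3 members of each list complete the rule. Some genes that the rule names are not reported here. Genes past the additive test, receptor segments, Xist, Y-linked and nuclear RNA genes and library composition were named after their values were seen. The lists, the tests, the naming rule and most alternative settings were chosen before the data were examined.

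The alternative settings chosen in advance were median-of-ratios factors, library size alone, other filters, prior counts of 0.5 and 10, DESeq2 1.42.0, limma-voom, models without the other factor, each library left out with that factor dropped, special gene classes left out, Spearman correlation, an estimated correlation in camera, and fry. After the data were seen, offsets for gene length and GC share (mgcv 1.9.3, GC share known for 97.8% of identifiers) and a fit without markers of cells other than T cells and receptor segments were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots. An interaction of age and genotype was not tested, since it leaves no residual degree of freedom, and reads were not analysed here.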

Results

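Total RNA from splenic T cells of C57BL/6 mice was sequenced after activation for 3 days by antibodies to CD3 and CD28 in the presence of IL-2. The mice were wild type or lacked ceramide synthase 6 (Cers6), an enzyme that attaches fatty acyl chains to a sphingoid base to make ceramide, and were 2 or 8 months old. Per the labels the series asks how expression in aging depends on this enzyme. The 4 groups are wild type at 2 months, wild type at 8 months, Cers6 knockout at 2 months and Cers6 knockout at 8 months, and levels below are given in this order. Each group has 1 library, so no replicate check was possible within a group. The series text speaks of duplicate samples, and the labels do not say whether RNA of several mice was pooled. The libraries held 24239344, 21886108, 18145555 and 20342672 counts, with 13665, 13955, 12937 and 14413 genes at 10 or more counts. Levels are given as CPM, the normalised read count relative to library size, and all intervals are 95% intervals that cover counting error only. Tests come from an additive model of age and genotype, in which the 2 ages stand in for the replicates of a genotype and the 2 genotypes for those of an age. Its p-values rest on 1 residual degree of freedom and on a spread shared across genes. That spread mixes any real difference of the genotype effect between ages with differences between single libraries. No spread between mice of a group was measured.

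The transcript of the deleted gene was lower in both knockout libraries and remained detectable. Cers6 (ENSMUSG00000027035, GRCm38 chromosome 2, 68861441 to 69114282) measured 13.1 CPM (11.7 to 14.7), 32.0 CPM (29.6 to 34.5), 9.17 CPM (7.80 to 10.7) and 3.38 CPM (2.68 to 4.21). The knockout over wild type log2 fold was -0.51 (-0.80 to -0.23) at 2 months and -3.21 (-3.60 to -2.90) at 8 months. With age, Cers6 was higher in wild type (log2 1.28, 1.09 to 1.49) and lower in knockout (log2 -1.41, -1.85 to -1.04). The additive genotype effect of log2 -1.85 (SE 0.51) did not pass the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.392). The deleted part of the gene is not given in the sources used here, and counts over the whole gene include any transcript that lacks it. Among the other ceramide synthases, Cers4 (ENSMUSG00000008206, chromosome 8, 4493026 to 4531680) measured 35.5, 20.6, 29.3 and 43.5 CPM, with a knockout over wild type log2 fold of -0.28 at 2 months and 1.08 (0.92 to 1.24) at 8 months. Cers5 (ENSMUSG00000023021, chromosome 15, 99734881 to 99772885) measured 77.2, 73.7, 69.9 and 56.0 CPM. Cers2 (ENSMUSG00000015714, chromosome 3, 95314791 to 95323599) measured 86.0, 84.0, 76.1 and 80.6 CPM. Cers1 had at most 6 counts and Cers3 at most 1 count in any library. Neither the ceramide synthases (camera adjusted p = 0.187 for genotype and 0.952 for age) nor the 40 other measured genes of sphingolipid metabolism (camera adjusted p = 0.926 and 0.475) passed a list test, although the ceramide synthases passed as lower for genotype with offsets for gene length and GC share (camera adjusted p = 0.0397). The ceramide synthase list holds the deleted Cers6 among its 4 tested genes, so a lower result was partly set by the deletion. Its additive genotype effects had a mean of log2 -0.46 and a median of -0.19, without offsets. Of the single genes, 1 ceramide synthase, Cers6, passed as lower for genotype when adjusted over the list alone, against 0 over all genes (edgeR quasi-likelihood). Within that sphingolipid list, Galc, which breaks down galactosylceramide, had a knockout over wild type log2 fold of -0.03 at 2 months and 1.15 at 8 months, and S1pr2, a receptor for sphingosine 1-phosphate, had -0.11 and 1.23.

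**Figure D1:**
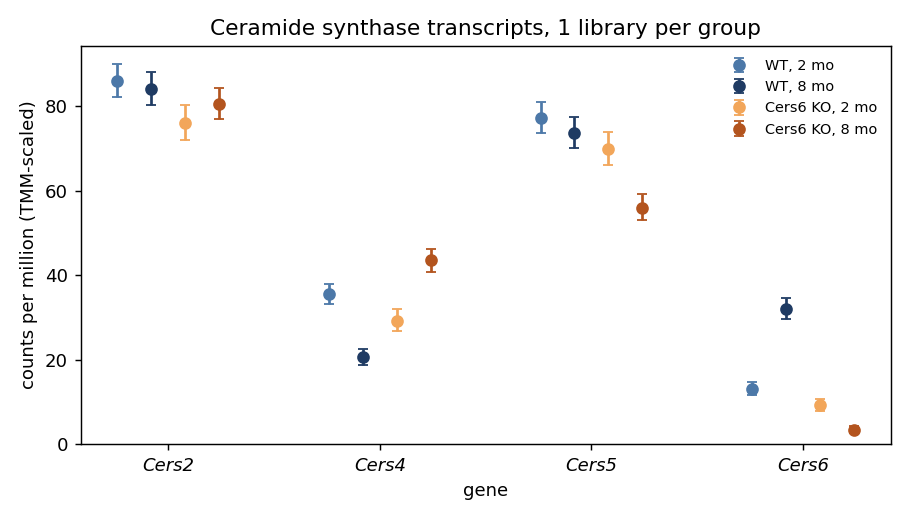
CPM of Cers2, Cers4, Cers5 and Cers6 in the 4 libraries, with bars for the 95% counting interval of each library. Cers6 lies at 13.1 and 32.0 CPM in the wild-type libraries and at 9.17 and 3.38 CPM in the knockout libraries.

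The comparison of knockout with wild type across both ages asks what loss of Cers6 does at either age. Kcna3, the voltage-gated potassium channel Kv1.3 of T cells (ENSMUSG00000047959, chromosome 3, 107036162 to 107038129), measured 11.4, 8.87, 32.9 and 36.0 CPM and rose by log2 1.78 (SE 0.29, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0451), a call that ended with median-of-ratios size factors (log2 1.76, edgeR adjusted p = 0.140). Il1rn, the interleukin-1 receptor antagonist (ENSMUSG00000026981, chromosome 2, 24336853 to 24351494), measured 4.31, 35.8, 0.755 and 3.68 CPM and fell by 2.96 on the log2 scale (SE 0.42, edgeR adjusted p = 0.0103). S100a8 and S100a9, which encode the calprotectin subunits abundant in neutrophils, had 6, 791, 0 and 23 counts and 11, 1074, 1 and 19 counts. They fell with fitted log2 changes of -5.24 (SE 0.61, edgeR adjusted p = 0.00131) and -5.70 (SE 0.60, edgeR adjusted p = 0.000622), where most counts lie in the wild-type library at 8 months and the size depends on the prior count. S100a8 is ENSMUSG00000056054 (chromosome 3, 90669071 to 90670034) and S100a9 is ENSMUSG00000056071 (chromosome 3, 90692632 to 90695721). These 4 genes, 1 higher and 3 lower, were all that passed among 13906 tested, and 1162 had an unadjusted p under 0.05. A filter at a mean of 5 CPM or more gave 69 higher and 32 lower. The count was 0 with library size alone as the scaling (938 at an unadjusted p under 0.05) and between 0 and 101 with each library left out, 101 without wild type at 2 months and 0 without wild type at 8 months, knockout at 2 months or knockout at 8 months (195, 4349 and 1192 at an unadjusted p under 0.05). Of the 2-fold genes, 63 were higher and 61 lower in knockout at both ages, against 11.7 and 16.3 for independent lists. Simulations with no effect gave 47.3 and 45.7. They also gave 45.25 genes higher at 2 months and lower at 8 months, where the data held 10, so their spread did not match these contrasts.

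Among the other named genes higher in knockout at both ages, Atp7a, the copper-transporting ATPase, had log2 folds of 1.23 (0.94 to 1.54) at 2 months and 1.91 (1.59 to 2.28) at 8 months. Dennd4c, a Rab guanine nucleotide exchange factor, had 1.0 (0.87 to 1.14) and 1.78 (1.65 to 1.93). Lmbrd2, Prrg4, Sptb, Ppp2r3a and Sntb1 lay between 1.01 and 1.94 in both contrasts. The Y-linked Uty had 1.48 and 1.11, and the list of sex-linked genes rose with the knockout (4 tested, camera adjusted p = 5.13e-07, adjusted p = 0.847 with an estimated correlation, 4 genes past the test adjusted over the list alone and 0 over all genes). The wild-type library at 2 months held 440.5 CPM of Xist, the long RNA of the inactive X chromosome, against 0.0472, 0 and 0.171 CPM in the other 3. Among the named genes lower at both ages, Eps8l1, an adaptor of actin remodelling, had 139, 592, 2 and 150 counts, a log2 fold of -4.87 (-8.76 to -3.82) at 2 months and -2.11 (-2.39 to -1.86) at 8 months. F10, coagulation factor X, had -2.05 (-3.21 to -1.30) and -4.12 (-5.02 to -3.60). Clec4n, Prg2, Pla2g7, Irg1 and Ccl9, genes expressed by myeloid cells or granulocytes, lay between -3.07 and -1.32 at 2 months and between -4.22 and -2.18 at 8 months. None of these genes passed the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p from 0.104 for Eps8l1 to 0.534 for Ppp2r3a). With offsets for gene length and GC share, Eps8l1 passed as lower (log2 -3.07, edgeR adjusted p = 0.0186).

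Across the fixed lists, genes of the respiratory chain and of cell division fell in knockout, with lower medians at 8 than at 2 months. All comparisons of lists here used camera with a preset correlation, which called 25 of the 50 lists for genotype, 5 higher and 20 lower. With an estimated correlation camera called 0 (adjusted p from 0.847 to 0.855 for these 25, 0 of 50 lists at an unadjusted p under 0.05), and fry called 0 (1 list at an unadjusted p under 0.05). Both checks rest on 1 residual degree of freedom and could hardly call a list after adjustment, so they decide little either way. The estimated correlation of the DNA replication genes, for example, was 1 for genotype and -0.0154 for age. The nuclear-encoded oxidative phosphorylation genes fell (camera adjusted p = 1.63e-17, adjusted p = 0.847 with an estimated correlation), with 66 of 74 lower at 2 months and 73 of 74 at 8 months, medians of -0.18 and -0.70. The ATP synthase subunit Atp5g1 had -0.24 and -1.38, and the cytochrome c oxidase subunit Cox5b -0.26 and -1.15. The mitochondrially encoded genes fell (medians -0.26 and -0.90, camera adjusted p = 0.00453, adjusted p = 0.847 with an estimated correlation), among them mt-Nd1 at -0.48 and -1.32, and so did the mitochondrial ribosome list (medians -0.17 and -0.55, camera adjusted p = 0.000401). DNA replication genes fell (camera adjusted p = 2.16e-11, adjusted p = 0.847 with an estimated correlation), with medians of 0.03 at 2 months and -1.04 at 8 months. Mitosis genes fell as well (camera adjusted p = 0.00014, adjusted p = 0.852 with an estimated correlation), although 33 of 40 were higher at 2 months (median 0.20) and 40 of 40 lower at 8 months (median -0.66). None of the genes of these 5 lists passed on its own for genotype, adjusted over the list alone or over all genes (edgeR quasi-likelihood).

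Lists of protein production fell in the same test. The ribosome biogenesis and MYC targets had medians of -0.08 and -0.74 (camera adjusted p = 2.64e-07), with Srm, which makes spermidine, at -0.35 and -1.53. The cytosolic ribosomal proteins had -0.13 and -0.48 (camera adjusted p = 9.58e-06), the polyamine and one-carbon genes -0.01 and -0.61 (0.000953), the unfolded protein and integrated stress response genes -0.01 and -0.49 (0.0133), and the heat shock genes 0.01 and -0.50 (0.0235). The housekeeping genes also fell (medians -0.05 and -0.68, camera adjusted p = 3.11e-05), with 25 of 25 lower at 8 months. Antioxidant genes (medians -0.19 and -0.39, camera adjusted p = 0.00338) and antigen presentation genes (medians -0.22 and -0.33, camera adjusted p = 0.00671) completed these lists. Each had a camera adjusted p = 0.847 with an estimated correlation. Among random lists of matched expression, the antigen presentation median stood at percentile 0 at 2 months and 54.1 at 8 months. Genes of cyclic AMP and protein kinase A signalling rose (medians 0.10 and 0.33, camera adjusted p = 0.00477, adjusted p = 0.847 with an estimated correlation), with the phosphodiesterase Pde4d at 0.38 and 0.95 and the anchoring protein Akap9 at 0.40 and 0.89. T helper 1 genes rose (camera adjusted p = 0.00691), as did CD4 T cell genes (0.0116) and interferon-stimulated genes (0.0268), with adjusted p values of 0.847, 0.847 and 0.855 with an estimated correlation. Adjusted over the list alone, 1, 2 and 1 of their genes were higher, against 0, 0 and 0 over all genes (edgeR quasi-likelihood), and with library size alone the lists no longer passed camera (adjusted p = 0.0729, 0.0532 and 0.0701). Their medians at 2 months were -0.19, 0.11 and -0.10 and at 8 months 1.0, 0.42 and 0.45. The wild-type library at 8 months, against which the latter stand, took 98.6% of its Trbv counts from Trbv14, and with age in wild type these lists had medians of -1.09, -0.49 and -0.50. Knockout over wild type log2 folds were correlated across 12080 genes with gene length (Spearman 0.375 at 2 months and 0.301 at 8 months) and with GC share (-0.345 and -0.0755), where genes are not independent replicates. With offsets for both, the cyclic AMP, integrated stress response, antigen presentation and ribosomal protein lists no longer passed camera (adjusted p = 0.141, 0.0515, 0.0621 and 0.141), and the medians of oxidative phosphorylation and ribosomal protein genes at 2 months were 0.00 and 0.04.

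Markers of B cells and of several myeloid cells fell in knockout beside these groups, while other marker lists did not. NK cell genes had medians of -0.43 at 2 months and 1.70 at 8 months, erythroid genes 0.06 and 0.79, platelet genes -0.62 and 0.14, and stromal genes -0.22 and 0.28 (-0.17 with length and GC offsets), and none of these 4 lists passed for genotype (camera adjusted p = 0.677, 0.0645, 0.557 and 0.874), although the erythroid list passed as higher with those offsets (camera adjusted p = 0.00372). B cell genes fell (22 measured, medians -0.23 at 2 months and -1.11 at 8 months, camera adjusted p = 6.99e-11, adjusted p = 0.847 with an estimated correlation). Cd79a, part of the B cell receptor, measured 746.8, 964.3, 586.4 and 321.4 CPM, and Fcer2a had log2 folds of -0.10 and -2.80. The T cell gene Cd3e measured 344.6, 324.1, 346.6 and 232.8 CPM. The libraries thus held much B cell RNA beside that of T cells, and a change of a list need not lie in T cells. Neutrophil genes fell (10 measured, camera adjusted p = 6.99e-11), with medians of -1.25 at 2 months, or -0.62 with its 6 members at 0 in a library set to their bound, and -3.07 at 8 months. Monocyte and macrophage genes fell (16 measured, medians -0.50 and -1.22, camera adjusted p = 1.01e-09), as did mast cell and basophil genes (9 measured, -0.82 and -0.84, camera adjusted p = 9.63e-05). The wild-type library at 8 months was high in neutrophil and monocyte genes, with median log2 folds over 2 months of 4.99 and 1.30. With age in knockout these medians were 2.54 and 0.35, and the neutrophil gene Lcn2 measured 0.131, 7.65, 0 and 1.71 CPM. The 8-month medians for genotype thus rest largely on that single wild-type library. Adjusted over the list alone, 7 neutrophil genes and 8 monocyte and macrophage genes were lower, against 2 and 0 over all genes (edgeR quasi-likelihood). Plasma cell genes (medians -0.23 and -0.17, the latter 0.07 with library size alone, camera adjusted p = 0.00166), dendritic cell genes (-0.25 and -0.35, 0.00749) and gamma delta T cell genes (-0.49 and -0.70, 0.0459) fell too, each with an adjusted p = 0.847 with an estimated correlation. Of their members, 1 of 22 B cell genes, 3 of 18 neutrophil genes, 1 of 29 monocyte and macrophage genes, 2 of 15 plasma cell genes and 3 of 18 dendritic cell genes stand in another list as well.

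At 2 months cytokine and inflammatory genes were lower in knockout, beside markers of myeloid cells. Of 12133 genes, 112 were at least 2-fold higher and 252 at least 2-fold lower in knockout, and 29.85 genes at 2-fold were obtained on average in simulations with counting error alone. Cytokine and cytotoxic genes were lower (17 of 19, median -0.53, below all of 10000 random lists of matched expression), among them Gzma, a granule protease of cytotoxic cells, at log2 -1.08 (-1.16 to -0.99). Inflammatory secretory genes were lower in 13 of 13 (median -0.46, or -0.39 with its member at 0 set to its bound). Beside them, neutrophil genes were lower in 9 of 10, mast cell and basophil genes in 8 of 9 (median -0.82), platelet genes in 5 of 6 (median -0.62) and monocyte and macrophage genes in 15 of 16 (median -0.50). Interferon-stimulated genes had a median of -0.10, with the antiviral membrane protein gene Ifitm3 at -1.66. NK cell genes were lower in 13 of 16 (median -0.43), CD8 T cell genes in 10 of 14 (median -0.21) and T helper 1 genes in 11 of 13 (median -0.19). Fatty acid synthesis genes were higher in 12 of 14 (median 0.28), and naive and memory T cell genes in 25 of 31 (median 0.20). A single library stood on each side, so the contrast has no test.

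At 8 months the knockout library differed more widely from wild type. Of 12133 genes, 1266 were at least 2-fold higher and 785 at least 2-fold lower, against 3.6 from counting error alone. With library size alone as the scaling, 82.3% of the 2-fold genes were higher in place of 61.7%, since the median of all genes then stood at log2 0.25. NK cell genes had a median of 1.70 (16 measured, 11 higher), with the activating receptor Klrk1 at 3.03, and 5 of its members had no count in the wild-type library. T helper 1 genes were higher in 11 of 13 (median 1.0, above all of 10000 random lists), led by the interleukin-18 receptor chains Il18r1 at 2.54 and Il18rap at 2.51. Interferon-stimulated genes were higher in 40 of 59 (median 0.45), among them Pydc3 at 2.89 and Gbp6 at 1.85. The co-receptor Cd4 stood at 3.03, with 24.6 CPM in wild type and 201.7 CPM in knockout. The wild-type library of this contrast carried almost a single T cell receptor beta segment, described with the age comparison in wild type. In the other direction, DNA replication genes were lower in 39 of 39 and mitosis genes in 40 of 40, among them thymidylate synthase Tyms at -1.58, the ribonucleotide reductase subunit Rrm2 at -1.30 and the anaphase activator Cdc20 at -1.60. Lactate dehydrogenase Ldha stood at -1.57 and the glycolytic enzymes Tpi1 at -1.71 and Pfkl at -1.76, while the glycolysis list as a whole had a median of -0.35 and did not pass for genotype (camera adjusted p = 0.0636). The nuclear long RNAs Malat1 and Neat1 measured 1283 and 830 CPM in wild type and 2661 and 1425 CPM in knockout. No test was possible for this contrast alone.

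The comparison of 8 with 2 months in wild type asks how activated splenic T cell samples of normal mice differ with age. NK cell genes had a median log2 fold of -3.66, or -3.48 with the 5 members at 0 set to their bound, and 12 of 16 were lower. The inhibitory receptor gene Klrc1 had -5.05 (-6.47 to -4.39), and Klra7, another receptor of the NK gene complex, was at least 70.4-fold lower, with 229 counts at 2 months and 0 at 8 months. Klrk1 stood at -3.05, perforin Prf1 at -2.45 and the transcription factor Eomes at -2.22. T helper 1 genes were lower in 12 of 13 (median -1.09), cytokine and cytotoxic genes in 14 of 19 (median -1.01), CD8 T cell genes in 10 of 14 (median -0.82), interferon-stimulated genes in 49 of 59 (median -0.50) and CD4 T cell genes in 7 of 9 (median -0.49), each below all of 10000 random lists. Of these lists, 7 of 20 NK cell genes, 10 of 15 CD8 T cell genes, 4 of 9 CD4 T cell genes and 5 of 13 T helper 1 genes are held by another list. Neutrophil genes were higher in 10 of 10 (median 4.99), B cell genes in 22 of 22 (median 0.52), and monocyte and macrophage genes in 14 of 16 (median 1.30). In all, 399 genes were at least 2-fold higher and 336 at least 2-fold lower, against 14.65 from counting error alone.

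T cell receptor use set the wild-type library at 8 months apart from the other 3. Trbv14, a variable segment of the receptor beta chain, took 44007 of its 44622 Trbv counts, 98.6% (98.5 to 98.7, exact Clopper-Pearson), against 5.12% (4.46 to 5.85), 5.14% (4.43 to 5.93) and 7.40% (6.48 to 8.40) in wild type at 2 months, knockout at 2 months and knockout at 8 months. All other Trbv genes together measured 29.0 CPM there, against 165, 191 and 117 CPM. Trav7d-5, an alpha chain segment, took 35.5% (32.1 to 39.0) of its Trav counts, against 0.380%, 0.451% and 0.993%. The beta constant gene Trbc2 had 69571 counts against 9297, 6239 and 5024, while the alpha constant gene Trac had 3253 against 3778, 2706 and 2629. The co-receptor Cd8a measured 556.1 CPM in this library against 462.6, 536.2 and 412.0 CPM, and Cd4 24.6 CPM against 114.7, 127.0 and 201.7 CPM. These segments were picked after their values were seen.

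**Figure D2:**
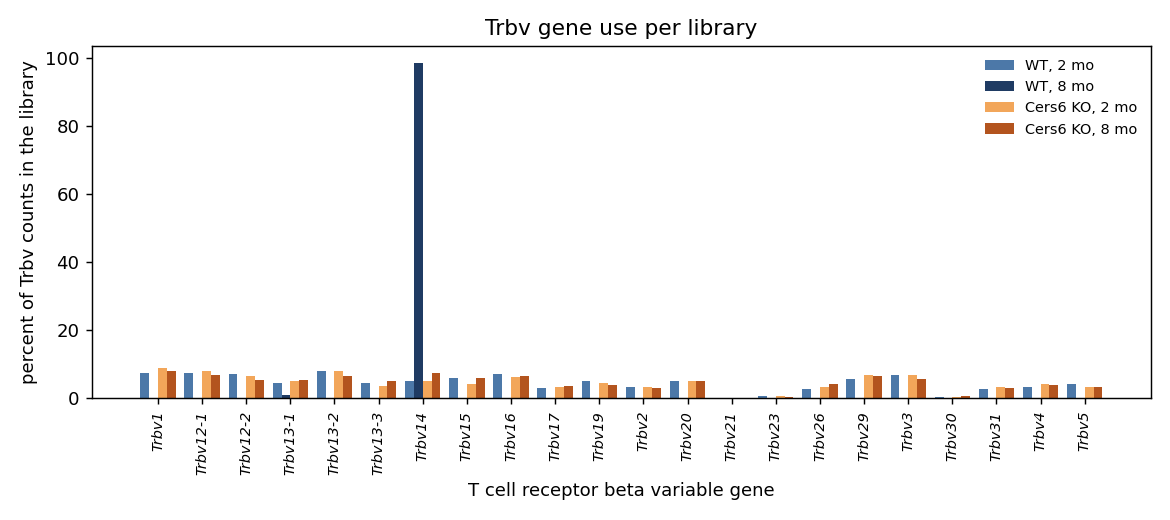
Percent of each library's Trbv counts taken by each T cell receptor beta variable gene, as bars from 0 with the 4 libraries side by side. Trbv14 takes 98.6% in wild type at 8 months and 5.12% to 7.40% in the other 3 libraries.

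The comparison of 8 with 2 months in knockout asks the same of Cers6-deficient samples. They also held B cell transcripts, with Cd79a at 586.4 CPM at 2 months and 321.4 CPM at 8 months. The changes below therefore need not lie in T cells. Cell division genes were lower, mitosis genes in 40 of 40 (37 of them at least 2-fold, median -1.42) and DNA replication genes in 39 of 39 (29 at least 2-fold, median -1.28). Cenpf, a kinetochore protein, stood at -1.71 and cyclin A2, Ccna2, at -1.78. Glycolysis genes were lower in 27 of 32 (median -0.64), oxidative phosphorylation genes in 71 of 74 (median -0.70), and ribosome biogenesis genes in 31 of 32 (median -0.54). NK cell genes had a median of -0.16 (0.11 with library size alone), T helper 1 genes of 0.23 and interferon-stimulated genes of 0.04. Platelet genes were higher in 5 of 6 (median 2.82), erythroid genes in 8 of 9 (median 1.66) and inflammatory secretory genes in 10 of 13 (median 1.82, or 1.15 with the member at 0 set to its bound). The T cell identity genes had a median of -0.40, with Cd3e, a signalling chain of the receptor complex, at 347 CPM at 2 months and 233 CPM at 8 months. Malat1 measured 898 CPM at 2 months and 2661 CPM at 8 months. Of 12133 genes, 1251 were at least 2-fold higher and 572 at least 2-fold lower, against 10.9 from counting error alone, and with library size alone 87.6% were higher in place of 68.6%, the median of all genes then being log2 0.24.

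Across both genotypes, Gzma and Gzmb, which encode granule proteases of cytotoxic T cells, fell with age, and markers of granulocytes and macrophages rose. Gzmb (ENSMUSG00000015437, chromosome 14, 56258856 to 56262260) measured 958.6, 123.3, 926.8 and 194.2 CPM and fell by 2.59 on the log2 scale (SE 0.35, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00187). Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100979) measured 180.5, 23.4, 85.5 and 22.8 CPM and fell by 2.41 (SE 0.28, edgeR adjusted p = 0.000506). Ly6c2, a surface antigen of effector and memory CD8 T cells, fell by 2.38 (SE 0.38, edgeR adjusted p = 0.00992), the neurofilament gene Nefh by 2.51 (SE 0.43, edgeR adjusted p = 0.0151) and Dapl1 by 1.44 (SE 0.24, edgeR adjusted p = 0.0151). Of the genes that rose, Thbs1, the matrix protein thrombospondin, gained log2 3.43 (SE 0.39, edgeR adjusted p = 0.000332), with 9.36-fold in wild type and 11.3-fold in knockout. The macrophage elastase Mmp12 rose by 4.09 (SE 0.46, edgeR adjusted p = 0.000332) and the chemokine Ccl22 by 2.35 (SE 0.26, edgeR adjusted p = 0.000332). Il4i1, a secreted amino acid oxidase, rose by 2.29 (SE 0.30, edgeR adjusted p = 0.00153). Il1rn rose by 2.76 (SE 0.41, edgeR adjusted p = 0.00534).

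The other genes past the age test included markers of neutrophils, macrophages, basophils and eosinophils. S100a9 was 88.6-fold higher at 8 months in wild type, with log2 6.47 (5.88 to 7.73), and in knockout, where the 2-month library had 1 count, the log2 fold was 2.57 (1.15 to 9.18). S100a8 was 105-fold higher in wild type and at least 5.65-fold higher in knockout, where the 2-month library had none. The wild-type folds of S100a9 and S100a8 include the prior count and lie below the plain ratios of CPM. Lysozyme, Lyz2, had log2 folds of 4.82 (4.42 to 5.45) and 1.60 (0.98 to 2.43), and the basophil protease Mcpt8 3.60 (3.16 to 4.29) and 1.95 (1.19 to 3.10). The eosinophil granule gene Prg2 had 2.43 and 3.32, Eps8l1 2.19 and 4.95, and the chemokines Cxcl2 2.82 and 2.67 and Ccl9 3.03 and 2.20. Col4a1, Lcn2, Mmp8, Serpinb2, Prss34, Cxcl3, Ccl6, Cd14, Igj, Slc15a2, Csf2rb2, Cd63, Csf2rb and Ifitm1 rose as well. In all 32 of 13906 genes passed, 27 higher and 5 lower (68 and 58 at a mean of 5 CPM or more), and 1143 had an unadjusted p under 0.05 (edgeR quasi-likelihood). The count was 0 with library size alone (807 at an unadjusted p under 0.05) and 20 with median-of-ratios size factors, where Nefh, Lyz2, Mcpt8, Prg2, Eps8l1, Col4a1, Ccl6, Cd14, Slc15a2, Cd63, Csf2rb and Ifitm1 no longer passed (edgeR adjusted p from 0.0580 to 0.0933). It was 0 (425 at an unadjusted p under 0.05), 3308, 1 and 762 without wild type at 2 months, wild type at 8 months, knockout at 2 months and knockout at 8 months. Without wild type at 8 months, that age rested on the knockout library alone, so the count may reflect this library rather than age. Of the other genes named for age, the interferon-induced Ifit3 and Gbp2, Neb, Lcn4 and Anxa2 were lower in both genotypes. They fell by log2 1.03 or more in each contrast and did not pass (edgeR quasi-likelihood, adjusted p from 0.0524 to 0.166).

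**Figure D3:**
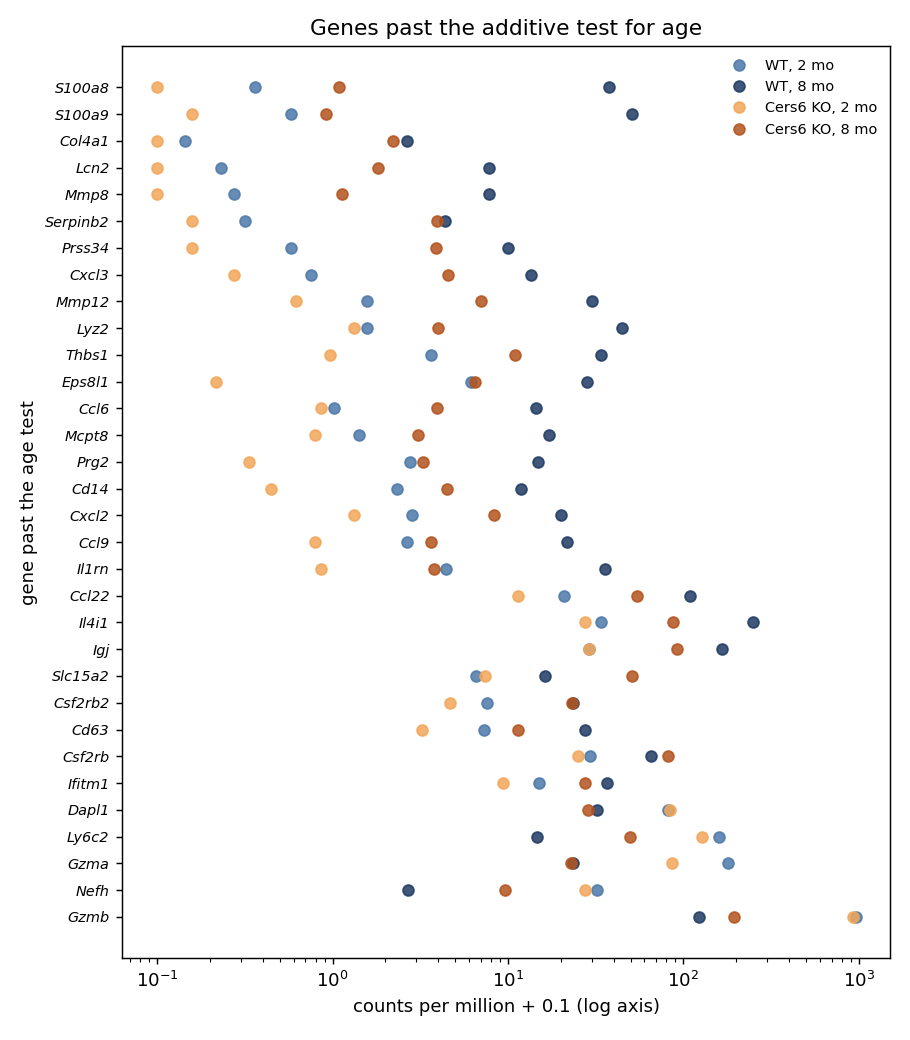
CPM plus 0.1, on a log axis, of the 32 genes past the additive test for age, with 1 point per library. Gzmb lies at 958.6 and 926.8 CPM at 2 months and at 123.3 and 194.2 CPM at 8 months.

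Among the lists, cell division and energy metabolism genes fell with age and markers of granulocytes, macrophages, platelets and erythroid cells rose. Camera with the preset correlation called 30 of 50 lists, 13 higher and 17 lower. With an estimated correlation it called 0 (adjusted p from 0.512 to 0.725 for these 30, 1 list at an unadjusted p under 0.05), and fry called 0 (10 lists at an unadjusted p under 0.05). As for genotype, 1 residual degree of freedom left both checks little able to call a list after adjustment. Mitosis genes fell (camera adjusted p = 2.58e-39, adjusted p = 0.512 with an estimated correlation), with 39 of 40 lower in wild type (median -0.36) and 40 of 40 in knockout. DNA replication genes fell (camera adjusted p = 4.34e-27, adjusted p = 0.512 with an estimated correlation), with 35 of 39 lower in wild type (median -0.22). Adjusted over the list alone, 38 mitosis genes and 25 DNA replication genes were lower, against 0 and 0 over all genes (edgeR quasi-likelihood, with 1143 genes at an unadjusted p under 0.05). Nuf2 of the kinetochore had -0.35 in wild type and -1.85 in knockout, and the DNA ligase Lig1 -0.34 and -1.81. Oxidative phosphorylation genes fell (medians -0.12 and -0.70, camera adjusted p = 3.72e-15, adjusted p = 0.512 with an estimated correlation), and glycolysis genes fell (medians -0.26 and -0.64, camera adjusted p = 3.6e-09, adjusted p = 0.55 with an estimated correlation). The housekeeping genes (medians -0.05 and -0.61, camera adjusted p = 6.14e-06) and ribosomal proteins (-0.07 and -0.44, 0.000231) fell too. So did polyamine genes (-0.03 and -0.73, 0.000392), cholesterol synthesis genes (0.00 and -0.36, 0.0284) and fatty acid synthesis genes (-0.06 and -0.32, 0.0456). Their camera adjusted p values were between 0.512 and 0.725 with an estimated correlation. Among random lists of matched expression, the ribosomal protein medians stood at percentiles 40.6 and 39.3. Those of fatty acid synthesis stood at 31.1 and 15.7, so neither list fell beyond genes of like expression. Ribosome biogenesis and MYC targets fell in the additive test (camera adjusted p = 0.000991, adjusted p = 0.512 with an estimated correlation), although their median was 0.09 in wild type and -0.54 in knockout.

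Lists of effector T cell and NK cell genes passed as lower with age in the additive test, and their lower medians stood in wild type, whose 8-month library carried almost a single receptor beta segment. In knockout the medians were -0.16 for NK cell genes (0.11 with library size alone), 0.08 for cytokine and cytotoxic genes, 0.23 for T helper 1 genes, 0.04 for interferon-stimulated genes and 0.01 for CD8 T cell genes. The NK cell list (camera adjusted p = 1.62e-06), the cytokine and cytotoxic list (5.76e-05), the T helper 1 list (0.00146), the interferon-stimulated list (0.00159), the CD8 list (0.00382), the naive and memory list (0.00382) and the T cell identity list (0.0202) passed as lower, with adjusted p values between 0.512 and 0.687 with an estimated correlation. The naive and memory list had medians of 0.00 in wild type and -0.26 in knockout (0.01 with library size alone) and the T cell identity list -0.20 and -0.40. Among random lists of matched expression, the naive and memory medians stood at percentiles 83.5 and 46.6, so they were not lower than genes of like expression. The T cell identity medians stood at percentiles 0.17 in wild type and 24.55 in knockout. Adjusted over the list alone, 4 NK cell genes, 5 cytokine and cytotoxic genes and 4 T helper 1 genes were lower, against 1, 2 and 0 over all genes (edgeR quasi-likelihood). In the same adjustment 1 NK cell gene and 2 cytokine and cytotoxic genes were higher, against 0 and 0 over all genes. Of the interferon-stimulated genes 1 was higher and 3 lower adjusted over the list alone, against 1 and 0 over all genes, and of the CD8 T cell genes 1 was lower, against 0. With offsets for length and GC share the T cell identity list no longer passed camera (adjusted p = 0.0637). Neutrophil genes rose (camera adjusted p = 4.12e-21), with a median of 2.54 in knockout, or 2.5 with the 6 members at 0 set to their bound. Monocyte and macrophage genes (camera adjusted p = 2.15e-10, median 0.35 in knockout), platelet genes (6.45e-09, median 1.54 in wild type), mast cell and basophil genes (3.23e-08, medians 1.30 and 1.11) and erythroid genes (4.33e-06, median 0.94 in wild type) rose, as did inflammatory secretory genes (7.99e-08, median 1.01 in wild type). Their adjusted p values were between 0.512 and 0.522 with an estimated correlation. Adjusted over the list alone, 9 neutrophil, 8 monocyte and macrophage, 6 platelet, 6 inflammatory secretory, 5 mast cell and basophil and 5 erythroid genes were higher, against 4, 2, 1, 2, 2 and 0 over all genes (edgeR quasi-likelihood). The inflammatory cytokine Il1b had log2 folds of 1.48 in wild type and 2.51 in knockout, and the platelet chemokine Pf4 1.79 and 3.18, and neither passed (edgeR adjusted p = 0.0543 and 0.0578). Plasma cell genes (medians 0.13 in wild type and 0.21 in knockout, camera adjusted p = 0.000253), dendritic cell genes (0.34 and 0.33, 0.000605), sex-linked genes (0.72 and 0.33, 0.000605), stromal and endothelial genes (0.12 and 1.01, 0.00433), T helper 2 genes (0.17 and 0.67, 0.00861) and T helper 17 and follicular helper genes (0.11 and 0.31, 0.0284) also rose. Gamma delta T cell genes passed as higher (camera adjusted p = 0.0471), although their median was 0.31 in wild type and -0.12 in knockout (0.14 with library size alone), where 4 of 8 were lower. These lists had adjusted p values between 0.512 and 0.55 with an estimated correlation. With library size alone the cholesterol synthesis and gamma delta lists no longer passed camera (adjusted p = 0.0610 and 0.0941). Only 3 of 20 stromal and endothelial genes were measured at 2 CPM or more.

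**Figure D4:**
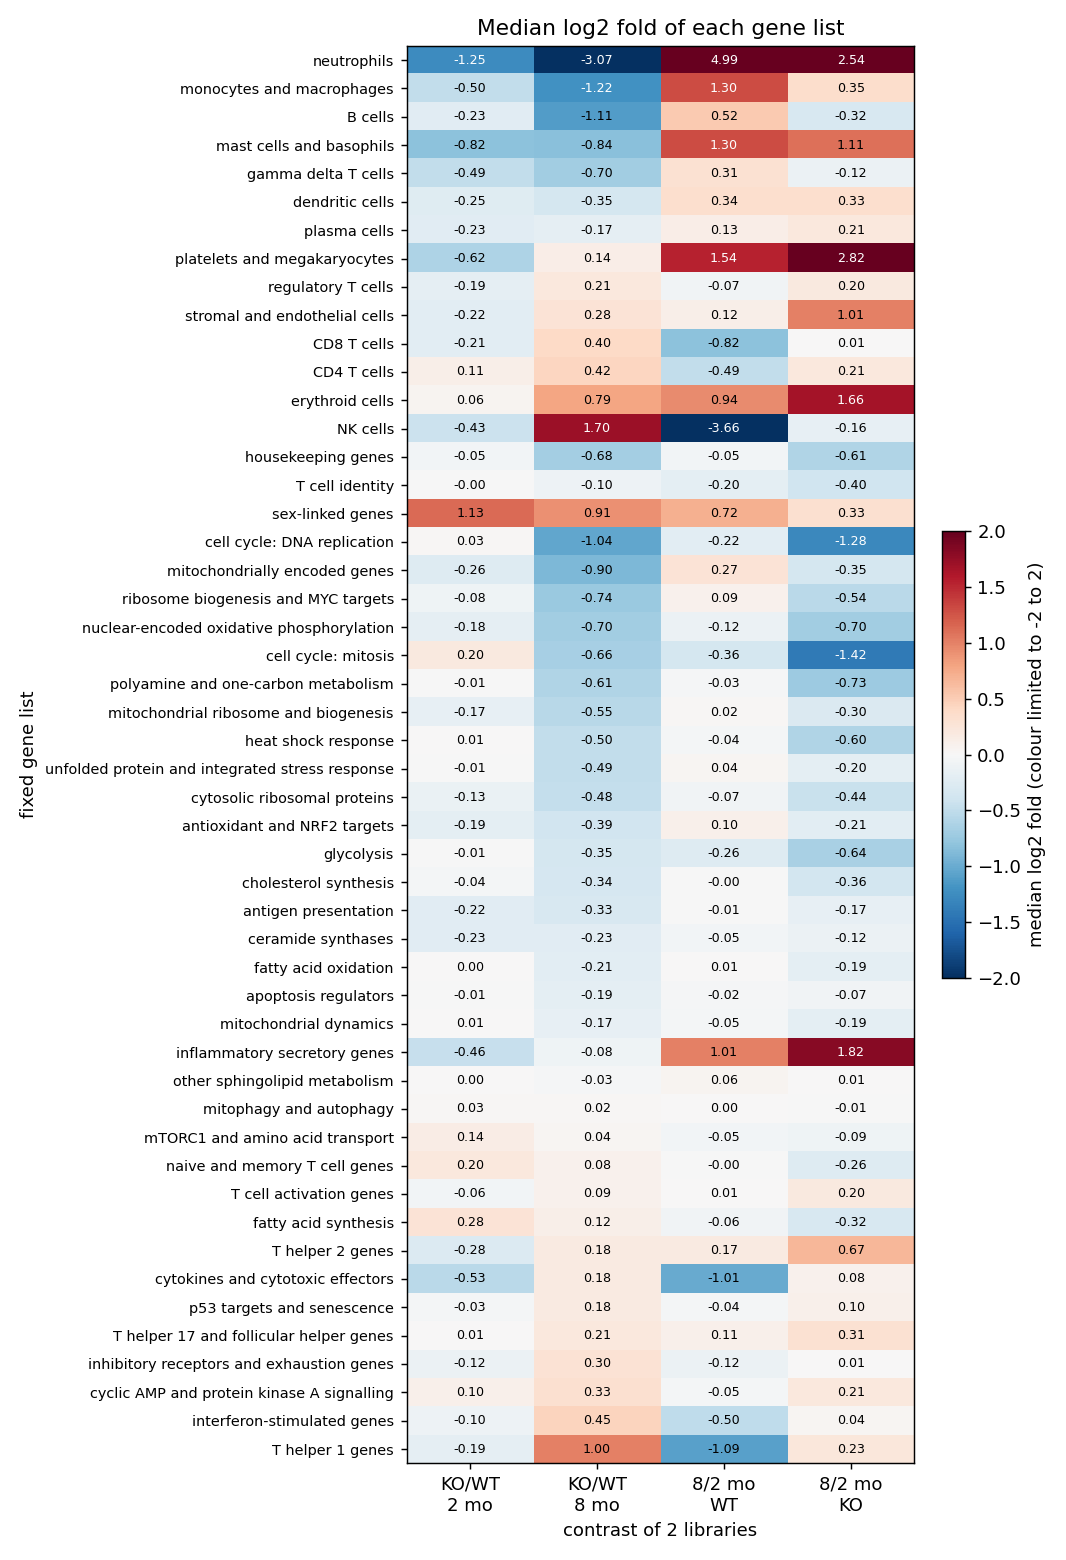
Median log2 fold of each of the 50 fixed gene lists in the 4 single-library contrasts, as a colour scale limited to -2 and 2. Mitosis genes stand at -1.42 for age in knockout and -0.36 in wild type, and NK cell genes at -3.66 for age in wild type and 1.70 for knockout over wild type at 8 months.

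Several other lists, mitochondrial quality control among them, passed for neither factor. The 42 mitophagy and autophagy genes had medians between -0.01 and 0.03 in the 4 contrasts under the main scaling (camera adjusted p = 0.874 for genotype and 0.675 for age), although Bnip3, a mitophagy receptor, had -0.45 with age in wild type and -1.09 in knockout. Mitochondrial dynamics genes (camera adjusted p = 0.525 and 0.297), fatty acid oxidation genes (0.277 and 0.415), mTORC1 and amino acid transport genes (0.26 and 0.402), p53 targets and senescence genes (0.779 and 0.952), apoptosis regulators (0.676 and 0.297), inhibitory receptors and exhaustion genes (0.664 and 0.238), T cell activation genes (0.262 and 0.675) and regulatory T cell genes (0.235 and 0.809) did not pass either. Median, mean and test differed in sign for the sphingolipid and p53 lists under genotype and for the integrated stress response, antioxidant, heat shock and ceramide synthase lists under age, none of which passed there.

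Whether the knockout effect was alike at both ages was asked across genes. The log2 folds at 2 and at 8 months were correlated with Pearson r = 0.136 over 12133 genes, where simulations with no effect gave -0.000309 (SD 0.0137) and genes are not independent replicates. At 2-fold, 63 genes were higher and 61 lower at both ages, against 47.3 and 45.7 in simulations with no effect and 11.7 and 16.3 for independent lists. The 2 opposite ways held 10 and 84 genes, against 45.25 and 46.58 simulated and 7.25 and 26.3 for independent lists. The simulations gave every library the spread of the additive fit and put nearly equal numbers in every direction, unlike the data. With offsets for length and GC share the correlation was 0.0733. For age, the wild-type and knockout folds had r = 0.187 (simulated 0.000977, SD 0.0114), with 186 genes higher and 29 lower in both genotypes. The 186 lay above and the 29 below the simulated 46.8 and 46.8, and both lay above the 41.1 and 15.8 of independent lists. Another 89 genes were lower in wild type and higher in knockout, against 46.91 simulated and 34.6 for independent lists. The reverse held for 8 genes, against 45.74 and 18.8. The age effect in wild type and the knockout effect at 8 months share a library with opposite sign, which alone gives a negative value. Their r of -0.521 stood beside -0.503 (SD 0.00960) in simulations with no effect, and their covariance of -0.280 beside -0.164. At 2-fold, 249 genes were lower with age in wild type and higher in knockout than wild type at 8 months, against a simulated 178.74, and 186 went the reverse ways, against 114.1.

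Some genes moved apart between genotypes with age, and no test of that difference was possible with 1 library per group. Dnm1, the endocytic GTPase dynamin 1, had a log2 fold of -2.97 (-4.52 to -2.21) in wild type and 2.66 (2.33 to 3.07) in knockout. Arhgef25 had -2.35 (-3.28 to -1.74) and 1.92 (1.58 to 2.32). Klrc1 had -5.05 and 0.21, and Samd3, with 333, 2, 137 and 127 counts, had an interval of -10.31 to -5.40 in wild type and of -0.91 to -0.19 in knockout. Klra7 was at least 46.9-fold higher in knockout than in wild type at 8 months. In the other direction, the gut-homing receptor Ccr9 had 2.65 (2.33 to 3.06) in wild type and -0.48 (-0.91 to -0.06) in knockout, the receptor gene Lifr 4.05 (3.62 to 4.71) and 0.94 (0.13 to 1.97), and the retinol-metabolising enzyme gene Dhrs4 0.29 (0.09 to 0.49) and -2.80 (-3.29 to -2.43). Xist, with 10117, 1, 0 and 4 counts, was at least 2529-fold lower in knockout than in wild type at 2 months. It was high in that wild-type library alone, where Y-linked genes were lower than elsewhere, so the sex of the cells may underlie this difference.

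The deposited tests of the authors, at an adjusted p-value under 0.005 and a log2 fold beyond 1, mark 231 genes for age in wild type (148 higher, 83 lower) and 311 for age in knockout (256 higher, 55 lower). They mark 5 genes for knockout over wild type at 2 months (1 higher, 4 lower) and 596 at 8 months (406 higher, 190 lower). The tool behind them is not given in the sources used here. The contrasts with 364, 735, 1823 and 2051 genes at 2-fold here were knockout over wild type at 2 months, age in wild type, age in knockout and knockout over wild type at 8 months, the same order as the authors' 4 counts.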

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

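All tests of explanations below were chosen only after the result was seen. The 11 differences here were picked because the 2 groups of a contrast went opposite ways, and with 1 library per group the difference was not tested for any of them.

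The knockout over wild type medians at 8 months minus those at 2 months were 2.13 for NK cell genes and 1.19 for T helper 1 genes. They were 0.62 for CD8 T cell genes and 0.55 for interferon-stimulated genes. With age in wild type the medians of these lists were -3.66, -1.09, -0.82 and -0.50, although 4, 1, 4 and 10 of their genes were higher. That contrast shares the 8-month wild-type library with opposite sign, which alone favours opposite directions but does not fix them. Mitosis genes, for example, were lower both with age in wild type (median -0.36) and in knockout at 8 months (median -0.66). A clone with an ordinary receptor level, as the source of the 98.6% of Trbv counts that Trbv14 took in wild type at 8 months, was argued against by receptor beta constant counts per Trac count 6.78 times the mean of the other libraries. A rearranged receptor expressed in most T cells of this library, such as a receptor transgene (the pmel-1 receptor uses segments of these families), may be the source, since the other Trbv genes stood at 0.184 of their mean elsewhere, but the labels name no transgene and whether it accounts for the effector genes was not tested. The age of this mouse, its genotype and its receptor use cannot be separated in 1 library, and this library enters both the age effect in wild type and the knockout effect at 8 months. A fit without it leaves the knockout library as the only one at 8 months, so it cannot separate age from genotype either.

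For mitosis genes the knockout over wild type median at 8 months minus that at 2 months was -0.86, and the median with age in knockout was -1.42. A trend with gene length and GC share as the whole cause was argued against, since the mitosis median at 8 months was -0.86 with offsets for both, against -0.66 without. A lower share of T cells as the whole cause of the fall with age in knockout was argued against by T cell identity genes at -0.40 there, which stayed above the mitosis genes. Shares of other cells or of dividing cells were not tested. B cell genes had medians of -1.11 for knockout over wild type at 8 months and -0.32 with age in knockout. A larger share of nuclear RNA cannot be told apart from a change in the cells, since 2 nuclear long RNAs were higher than in wild type at 8 months, Malat1 by log2 1.05 and Neat1 at 1425 against 830 CPM, and these levels alone do not separate the 2. Loss of Cers6 at 8 months stays open and untested, since 1 library stands for that group.

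Ribosome biogenesis and MYC target genes had an age effect in knockout that was -0.63 from that in wild type, and this difference was not tested. Among genes, the age effect in knockout minus that in wild type was -2.70 for Cers6, 5.63 for Dnm1, 4.26 for Arhgef25, -2.46 for the integrin gene Itgae and 2.25 for the interferon-inducible Pydc3, none of them tested.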

How the results depend on the processing

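Of the tests here, those with length and GC offsets and without markers of cells other than T cells were chosen only after the result was seen. None of the 61 tested gene results, and no list that passed camera, changed its direction under the alternatives run on it. With offsets, 6 lists changed direction for genotype (cytokine and cytotoxic, sphingolipid, mitophagy, p53, stromal and T cell identity). None of these passed camera for genotype with or without offsets. For genotype, where 4 genes passed edgeR quasi-likelihood, 1 higher and 3 lower, other settings gave 3 (median-of-ratios factors, without Kcna3), 5 (special gene classes left out), 8 (offsets, with all 4), 7 (without markers of other cells), 12 (limma-voom), 18 (DESeq2), 101 (mean of 5 CPM or more, 69 higher and 32 lower, all 4 shared), 135 (no filter, 76 higher and 59 lower, all 4 shared), and 0 with library size alone or no age term (938 and 804 at an unadjusted p under 0.05). With each library left out it ranged from 0 to 101, 101 without wild type at 2 months (48 higher and 53 lower, all 4 shared) and 0 without wild type at 8 months (195 at an unadjusted p under 0.05), knockout at 2 months (4349) and knockout at 8 months (1192). For age, where 32 passed, 27 higher and 5 lower, other settings gave 20 (median-of-ratios), 26 (without markers of other cells), 42 (special classes left out), 53 (offsets), 55 (limma-voom), 60 (DESeq2), 126 (mean of 5 CPM or more, 68 higher and 58 lower, 24 shared), 199 (no filter, 106 higher and 93 lower, all 32 shared), and 0 with library size alone or no genotype term (807 and 830 at an unadjusted p under 0.05). With each library left out it ranged from 0 to 3308, 0 without wild type at 2 months (425 at an unadjusted p under 0.05), 3308 without wild type at 8 months (1704 higher and 1604 lower, 27 shared), 1 without knockout at 2 months and 762 without knockout at 8 months (403 higher and 359 lower, all 32 shared). In these fits the lone library of an arm is assumed to vary like the others, and a count may reflect that library rather than the factor.

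Counts at 2-fold for knockout at 2 months, knockout at 8 months, age in wild type and age in knockout were 83, 1129, 270 and 910 at 10 CPM or more, where fewer genes are counted, and 2510, 5640, 3865 and 4899 with no filter, and a prior count of 10 gave 182 for knockout at 2 months. The correlation of the knockout effects between ages was 0.243 at 10 CPM, 0.0733 with offsets and 0.221 with Spearman, that of the age effects 0.149 with Spearman, and that of the third comparison -0.502, -0.536 and -0.316 in the same order and -0.479 without special gene classes. The lists passing for genotype and age were 22 and 29 with library size alone, 23 and 29 with offsets (21 and 29 of them among the lists that passed before, as were 22 and 28 with library size alone), and 0 and 0 with an estimated correlation and with fry. For the estimated correlation and fry, 1 residual degree of freedom left little power to call a list after adjustment. Of the 61 tested gene results, 13 lost their call with median-of-ratios factors and 36 with library size alone, and 5 gained one with offsets. The lists losing a call with library size alone were T helper 1 (adjusted p = 0.0729), interferon-stimulated (0.0701) and CD4 genes (0.0532) for genotype, and cholesterol synthesis (0.0610) and gamma delta genes (0.0941) for age, and with offsets T cell identity for age (0.0637) besides those given above. Lists gaining a call were ceramide synthases (0.0397, lower, with the deleted Cers6 in the list) and erythroid genes (0.00372, higher) for genotype with offsets, and B cell genes (0.00578, higher) for age with library size alone. The cause of these changes was not tested beyond the number of genes and libraries used. The pseudocounts set for a table of normalized values were not run, since the table holds counts, and prior counts were run in their place. No paired analysis was possible because each group has 1 library. A gene with no count in a library gives a bound only, and 1 to 3 counts give wide intervals.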

Other observations

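The tests of explanations in this part were chosen only after the result was seen, while the edgeR test for age was chosen before. Ighm, the constant region of immunoglobulin M, stood at 2503, 4173, 2264 and 2509 CPM in wild type at 2 and 8 months and knockout at 2 and 8 months. The alpha and beta globin genes Hba-a1 and Hbb-bs had additive age effects of log2 1.34 and 1.24, and neither passed edgeR quasi-likelihood. Ncr1, a receptor gene of NK cells, had 12, 8, 6 and 4 counts, and many other genes of the NK cell list are also expressed by activated T cells. The anti-inflammatory cytokine Il10 had log2 folds with age of -0.18 in wild type and 1.67 in knockout, and the prostaglandin synthase Ptgs2 1.01 and 2.42.

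Xist had 10117 counts in wild type at 2 months and 1, 0 and 4 in the others, while the 4 Y-linked genes Uty, Kdm5d, Ddx3y and Eif2s3y were counted in every library. Female cells alone were argued against by 515 counts of Ddx3y in wild type at 2 months. Female and male cells mixed in that library may be the source, since the Y-linked genes stood at a median of 0.388 of their mean in the other libraries. Xist expressed in male cells cannot be told apart from this, since the Y-linked genes stood at 0.575 of their lowest level elsewhere and the other 3 libraries themselves spread by a median of 1.73-fold. The labels give no sex, and the sex-linked list enters the genotype and age tests.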
